A study of Mus musculus with 2 samples.

How the data were processed

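Epithelial cells of the crypts of the proximal small intestine were profiled in male C57BL6/J mice of 2 months (young) and 20 months (old), with 3 mice per age per the labels. EpCAM-positive cells were sorted, 8000 cells were loaded per channel, and libraries were made with the 10x Single Cell 3' kit, version 2. Reads were processed with Cell Ranger 2.1.0 against the mm10 build, per the submitters' processing notes. The deposited matrix held counts: whole-number UMI counts for 28816 genes in 7718 cells of both ages, with 107002854 UMIs in all. A second deposited table gave each barcode an age and 1 of 10 cluster names; these 2 columns hold text in place of a measured unit, and the authors' method of clustering was not stated. How cells and genes were filtered before deposit was not stated either. The labels give a recovery of 3859 cells per channel, beside 4014 young and 3704 old barcodes in the matrix, and all of these were used.

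The barcodes carried 2 suffixes, 1 per age, so that each age was 1 library of pooled mice and the deposited files gave no map from cells to mice. The test between libraries that had been planned in case such a map existed gave no result for that reason. With 1 library per age, nothing was tested between ages: no p-value was computed, cells were not used as replicates, and library and age cannot be separated. Sums of counts carry exact Poisson 95% intervals and shares of cells carry exact Clopper-Pearson 95% intervals; all intervals cover counting error only. A count of 0 was set against a floor of 3 counts, taken over the group of cells summed, which gives the "at least" folds. These folds are not lower 95% bounds. For Gkn2 over all cells the exact interval of the ratio began at 76.5, under the 94.8-fold given below. The floor was 0.0515 CPM (UMI counts scaled to the same total) in the young library and 0.0615 CPM in the old library.

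Gene names were matched to the GRCm38 (mm10) annotation: 23656 names matched directly, 1629 matched once a hyphen or a leading letter lost in the deposited table was restored, and 3531 had no match and are given without a position. Of all genes, 10389 were never counted and 12208 had at least 50 counts over both ages, the minimum for ranking. Counts that 3' reads of close paralogs share (the H2-Q, Defa, Reg3 and Gbp families) are uncertain between family members.

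For the comparison over all cells, counts were summed per age and cluster, turned into CPM, and averaged over the 10 clusters with weights equal to the mean of each cluster's 2 age shares (direct standardisation; each cluster had at least 20 cells per age). The log2 ratio of old to young was taken with a pseudocount of 1 CPM, and its interval came from 1000 Poisson draws of the counts. Within a cluster of at least 50 cells per age, the same ratio was taken from the plain sums; the Tuft cluster had 29 young cells and was given for lists only. In text, folds within clusters are ratios of CPM with an interval and no pseudocount.

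The rule for named genes, the gene lists, the markers and the first set of other settings were fixed before the data were examined. Over all cells, the rule took the 12 genes with the largest and the 12 with the smallest log2 ratio among those with at least 50 counts, with Poisson intervals of the 2 ages apart, and with the same sign in at least 80% of clusters. In the Stem cluster it took 10 each way without the condition on clusters, and in the other clusters 3 each way. Of each list it took up to 4 members with extreme ratios and any member needed to describe the list. A list's median log2 ratio was set against 10000 random lists of the same size matched on expression in 20 bins, and its percentile among them describes these libraries only. The 18 lists were interferon gamma response, type I interferon response, MHC class II, MHC class I, antimicrobial and mucosal defence, Wnt target and stem, Notch and secretory fate, cell cycle, fatty acid oxidation, cholesterol synthesis, lipid absorption, unfolded protein response, immediate early and heat shock, p53 and senescence, NF-kB and chemokine, oxidative stress defence, ribosomal protein and mitochondrially encoded. The 12 marker lists were for stem, cycling, enterocyte, Paneth, goblet, enteroendocrine and tuft cells, for T and intraepithelial lymphocytes, B and plasma cells, myeloid cells, stromal and endothelial cells, and red blood cells. Lists of glucocorticoid targets, clock genes and gastric genes were written after the first look at the values.

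The first set of other settings held a plain sum over cells, equal weights for clusters, TMM and median-of-ratios scaling, each cell scaled to the same total, Paneth and goblet genes left out of totals, no minimum or 200 counts, pseudocounts of 0.1 and 5 CPM, Scrublet doublets left out, the lowest and highest 10% of cells by UMIs left out, cells thinned to 3600 UMIs, and an own clustering (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, which gave 21 clusters, each named by the deposited cluster most of its cells came from). Scrublet's automatic threshold marked 1 young and 1 old cell and so did not work on these data, and leaving out the 3% of cells of each age with the highest scores was added after the data were seen. Further settings added then were a common floor of 4997 UMIs per cell (the lowest young total), that floor with cells over 10% mitochondrial UMIs left out, cells with UMIs of at least 3 lymphocyte or 3 myeloid markers left out, the Secretory Progenitors cluster left out, Stem cells with at least 3 enteroendocrine markers left out, and the cell richest in Paneth marker UMIs left out of 2 clusters. Shares of cells with a UMI were taken after thinning to 3600 UMIs, a depth every cell reached.

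The procedure was tested on simulated data with changed genes at 3 sizes. The direction was recovered for 100% of the 67 genes changed 1.5-fold, the 67 changed 2-fold and the 66 changed 4-fold, and 73.1%, 83.6% and 90.9% of them met the conditions of the rule. Of 12008 unchanged genes, 2.07% met the conditions too, with an absolute log2 ratio of at most 0.39; the bound set for that share had been lower and was loosened once this value was seen. A list changed 2-fold reached percentile 100, 1 of 40 unchanged lists lay outside the central 95% of random lists, and 95.4% of Poisson intervals covered the true value. The simulated counts were Poisson draws with no added spread between cells, so that coverage follows from how they were drawn. It does not show that the intervals or the rule hold for genes whose counts lie in few cells. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.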

Results

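The data were UMI counts of single EpCAM-positive cells from small-intestinal crypts, in 1 young library (4014 cells) and 1 old library (3704 cells), each from 3 pooled male mice. The young library held 58246144 UMIs with a median of 13715.5 UMIs and 3441 genes per cell, and the old library held 48756710 UMIs with a median of 12842 UMIs and 3303 genes per cell. The lowest UMI total of a cell was 4997 in the young library and 3693 in the old library, and 457 old cells lay under the lowest young total. The median mitochondrial share was 4.24% in young cells and 4.00% in old cells. There was no replicate library at either age, so every difference below is a difference between 2 libraries, its interval covers counting error only, and no spread between replicates can be set beside it. The series title names transcription in the ageing mouse intestine as its subject, and the comparison asks which genes and cell types of the crypt differed between the ages.

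Over all cells at a common cell composition, the largest differences were in genes of antigen presentation, which were higher in the old library. H2-Aa, a chain of the MHC class II molecules that show peptides to helper T cells, stood at 3.72 CPM in the young and 449 CPM in the old library (log2 ratio 6.58, interval 6.42 to 6.75), and it was higher in each of the 10 clusters. Its partner chain H2-Ab1 went from 31.3 to 811 CPM (log2 ratio 4.65), H2-Eb1, another class II chain, from 9.59 to 393 CPM (5.22), and Cd74, the invariant chain that escorts class II molecules, from 79.8 to 2052 CPM (4.67). The largest differences the other way were in Mptx1, a mucosal pentraxin, at 17.8 CPM in the young and 1.48 CPM in the old library (log2 ratio -2.92, interval -3.14 to -2.71), and in Nrn1, the neuronal surface protein neuritin, at 14.7 and 2.104 CPM (-2.34). The 627 young Mptx1 UMIs lay in 72 cells, with 19.1% of them in 1 cell and 574 of them in the Goblet cluster. Over all 12208 genes the median log2 ratio was -0.01.

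The other genes named as higher in the old library were mostly of the same kind. H2-DMb1 (2.61 to 87.3 CPM, log2 ratio 4.61) and H2-DMa (17.1 to 139.6 CPM, 2.96) encode the chaperone that loads peptides onto class II molecules, and Ciita (0.236 to 6.70 CPM, 2.64) is the transactivator of class II genes. Psmb8, an immunoproteasome subunit, stood at 121 and 689 CPM (2.49). H2-Q7, a nonclassical class I gene, stood at 4.00 and 53.9 CPM (3.46), and Igtp, an interferon-induced GTPase, at 2.76 and 26.0 CPM (2.85). Plet1, a surface protein of epithelia, stood at 0.321 and 11.7 CPM (3.27). Gkn2, a gastrokine secreted by surface cells of the stomach, had 0 counts in the young and 238 in the old library, at least 94.8-fold higher, and was spread thinly over the clusters in the old library, at 1 to 5 UMIs of Gkn1, Gkn2 and Tff1 per cell in 396 cells.

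Of the genes named as lower in the old library, Fkbp5 (20.8 to 4.82 CPM, log2 ratio -1.90) and Sgk1 (9.93 to 2.34 CPM, -1.71) are known targets of the glucocorticoid receptor. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, stood at 126 and 44.6 CPM (-1.48) and was lower in each of the 10 clusters. Wfdc10 (8.66 to 1.14 CPM, -2.18) and Wfdc2 (14.9 to 3.45 CPM, -1.83) encode whey acidic protein domain inhibitors, and Cox6b2 (16.3 to 3.99 CPM, -1.80) a subunit of cytochrome c oxidase. The remaining genes were Gm21814 (-1.94), 1700011H14Rik (-1.85, with no position in the annotation), Tceal8 (-1.78) and the long noncoding RNA E230001N04Rik (-1.54).

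**Figure D1:**
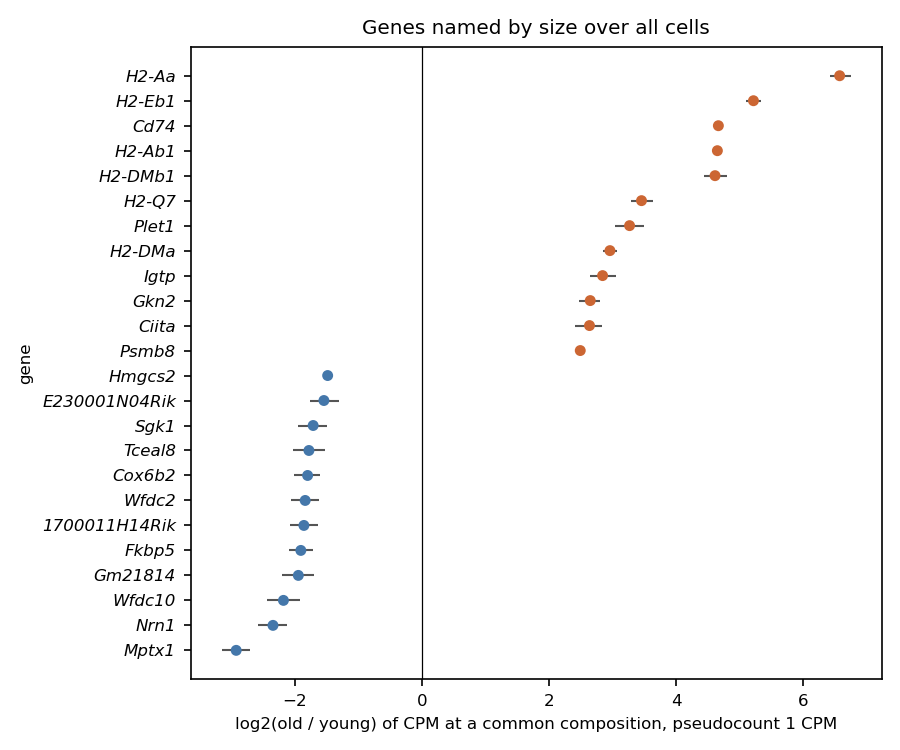
Log2 ratio of old to young CPM at a common cell composition (x axis, pseudocount 1 CPM) for the 24 genes named by size (y axis), points with 95% counting intervals as bars. Genes higher in the old library (orange) run from Psmb8 at 2.49 to H2-Aa at 6.58, and genes lower (blue) from Hmgcs2 at -1.48 to Mptx1 at -2.92.

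Most of the class II and class I genes lie together on mouse chromosome 17 (GRCm38). H2-DMa spans 34119693 to 34139101, H2-DMb1 34153191 to 34160229, Psmb8 34198195 to 34201454, H2-Ab1 34263227 to 34269418, H2-Aa 34282744 to 34287823, H2-Eb1 34305867 to 34316674 and H2-Q7 35439140 to 35443773. Cd74 lies on chromosome 18 (60803849 to 60812652) and Ciita on chromosome 16 (10480014 to 10531064), and both were higher as well. Several neighbours in the same region stood near 0, among them Brd2 (log2 ratio -0.06), Ring1 (-0.11) and Notch4 (0.01). Mptx1 lies on chromosome 1 (174330518 to 174332877), Nrn1 on chromosome 13 (36725622 to 36734477), Gkn2 on chromosome 6 (87373365 to 87379494), Fkbp5 on chromosome 17 (28398753 to 28486149), Sgk1 on chromosome 10 (21882184 to 21999903) and Hmgcs2 on chromosome 3 (98280431 to 98310738). All of these genes are annotated as protein coding.

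**Figure D2:**
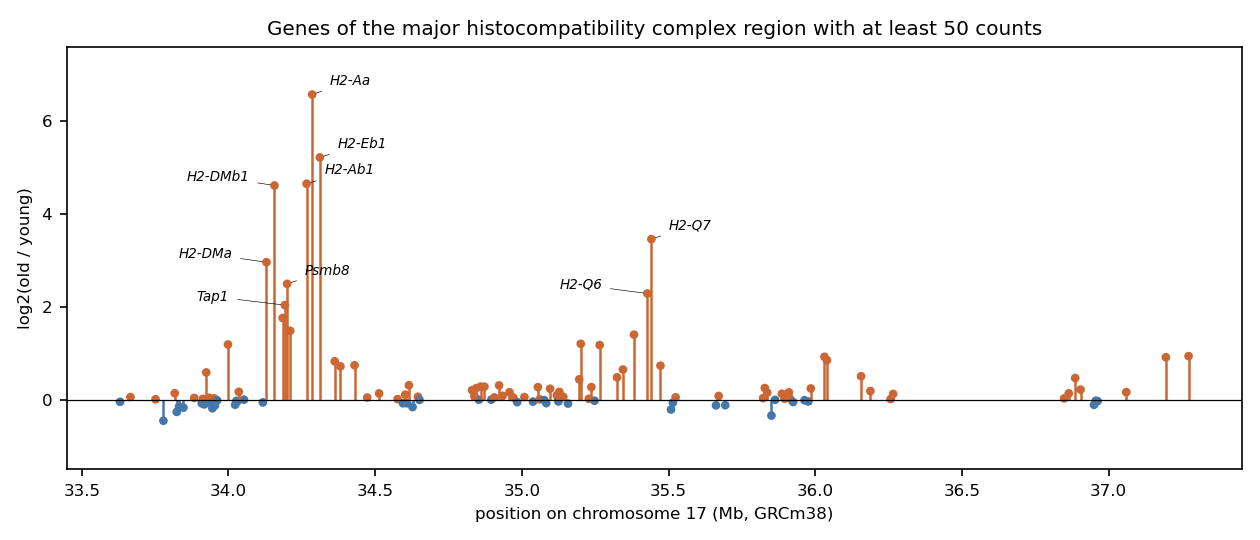
Log2 ratio of old to young CPM at a common composition (y axis) by position on chromosome 17 in megabases (x axis, GRCm38), 1 point per gene with at least 50 counts, orange above and blue below 0. The tallest points are H2-Aa at 6.58, H2-Eb1 at 5.22 and H2-Ab1 at 4.65, and Brd2 and Notch4 between or beside them stand at -0.06 and 0.01. Notch4 lies under the pseudocount, at 0.56 CPM in both ages, and the neighbour Btnl2 stands at 0.82.

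By list, the antigen presentation and interferon genes stood apart from expression-matched random lists. The MHC class II list had a median log2 ratio of 4.63 over 8 measured members (percentile 100), with 7 members at least 1.5-fold higher and Ctss, a lysosomal protease that trims the invariant chain, lowest at 0.37. The MHC class I list had a median of 1.17 over 13 members (percentile 100) with 10 at least 1.5-fold higher: the classical genes H2-K1 (314 to 715 CPM, 1.19) and H2-D1 (369 to 834 CPM, 1.17), the peptide transporter Tap1 (2.03), and B2m, the shared light chain, at 0.61. The interferon gamma response list had a median of 1.14 over 16 members (percentile 100) with 15 at least 1.5-fold higher, among them the transcription factors Stat1 (17.7 to 35.2 CPM, 0.95) and Irf1 (35.6 to 75.1 CPM, 1.06) and the GTPase Irgm2 (2.29). Iigp1, another interferon-induced GTPase, had 0 counts in the young and 154 in the old library, at least 61.3-fold higher. The type I interferon response list had a median of 0.53 over 17 members (percentile 100) with 7 at least 1.5-fold higher, from Ifitm3, an antiviral membrane protein, at 1.15 to Ifi27 at -0.39. With a pseudocount of 5 CPM that median was 0.25, and in Enterocyte the median was -0.05 over 5 members (percentile 45.4), with 3 of them below 0. The interferon gamma list holds Nlrc5, the transactivator of class I genes (3 and 128 counts, 1.88), and the immunoproteasome subunits Psmb8 and Psmb9 (1.76), which also serve class I presentation.

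Mucosal defence genes went both ways. The antimicrobial and mucosal defence list had a median of 0.13 over 16 members (percentile 99.9) with 7 at least 1.5-fold higher and 2 at least 1.5-fold lower. Reg3g and Reg3b, antibacterial lectins of the epithelium, stood at 697 and 2255 CPM (1.69) and at 702 and 1965 CPM (1.48) in young and old, and Nos2, the inducible nitric oxide synthase (1.82), Duox2 (1.68), a hydrogen peroxide producing oxidase, and its maturation factor Duoxa2 (1.75) were higher too. Mptx1 (-2.92) and the defensin Defa17 (168.6 to 96.3 CPM, -0.80) were lower, and Lyz1, the Paneth cell lysozyme, stood at 1774 and 1765 CPM (-0.01). The NF-kB and chemokine list had a median of 0.26 over 13 members (percentile 100) with 2 at least 1.5-fold higher, the cytokine Tnf (0.961 to 3.51 CPM) and the adhesion molecule Icam1 (0.83), and Ccl25, a chemokine of the small intestine, lowest at -0.32.

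Lists of metabolism differed less. Cholesterol synthesis had a median of 0.22 over 18 members (percentile 100) with 1 at least 1.5-fold higher, Pcsk9, which degrades the LDL receptor (0.93); Fdps, a synthase of the pathway, stood at 0.55 and Ldlr, the LDL receptor, at -0.33. Fatty acid oxidation had a median of -0.12 over 17 members (percentile 0.25) with 1 at least 1.5-fold lower, Hmgcs2 (-1.48), and the lipase inhibitor Angptl4 next at -0.46. Lipid absorption had a median of -0.05 over 16 members (percentile 9.69), with the apolipoproteins Apoa4 at -0.66 and Apoa1 at 0.36. Its medians by cluster went both ways: -0.31 in Early Enterocytes Progenitors (13 of 15 members below 0), -0.21 in TA and -0.15 in Late Enterocytes Progenitors, against 0.22 in Enterocyte (14 of 15 above 0).

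Over all cells, lists of stem cell signalling, growth and stress lay near 0. Wnt target and stem had a median of -0.06 over 16 members (percentile 8.32) with none at least 1.5-fold apart, from Ccnd1, a cyclin of cell cycle entry (0.36), to the ephrin receptor Ephb3 (-0.41); Lgr5, the receptor that marks crypt base stem cells, stood at 17.3 and 13.7 CPM (-0.32) and Olfm4, another stem cell gene, at -0.07. In a plain sum over all cells, which keeps the difference in composition, the median of this list was -0.30. Notch and secretory fate had a median of 0.02 over 13 members (percentile 70.0), with the Notch ligand Dll1 at 0.35 and the Notch target Nrarp at -0.60. Cell cycle had a median of -0.02 over 21 members (percentile 32.8), with Mki67, a marker of cycling cells, at -0.07. The medians were -0.05 for the unfolded protein response (14 members), -0.02 for immediate early and heat shock genes (17), -0.04 for p53 and senescence (14), with the cell cycle inhibitor Cdkn1a at -0.22, and -0.06 for oxidative stress defence (15). Ribosomal protein genes had a median of -0.04 over 82 members (percentile 0.02), with Rpl23a at 0.87 and Rpl9 at 0.66 the only members at least 1.5-fold apart, and mitochondrially encoded genes had a median of -0.02 over 13 members. Single clusters stood further from 0, and these differences between clusters were not tested. Immediate early and heat shock genes had a median of 0.52 in Enterocyte (14 members, 5 at least 1.5-fold higher), 0.36 in Secretory Progenitors and -0.60 in Tuft (8 members, 4 at least 1.5-fold lower). Cell cycle stood at -0.32 in Goblet (21 members, 7 at least 1.5-fold lower) and -0.66 in Paneth (5 members), and the unfolded protein response at -0.34 in Tuft and -0.30 in Paneth. Oxidative stress defence stood at -0.39 in Enteroendocrine (7 members) and Notch and secretory fate at -0.91 there (3 members).

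Marker lists, at the same common composition, showed small differences for most epithelial types: stem markers -0.16 (12 members), cycling markers -0.01 (12), enterocyte markers -0.21 (12), Paneth markers -0.22 (12), goblet markers 0.09 (12), enteroendocrine markers 0.53 (12) and tuft markers 0.29 (11). Gkn3, a stem cell marker, stood lowest of its list at -0.99. Among enteroendocrine markers, Ghrl, the hormone ghrelin, was lower (-1.43) and Tac1, a tachykinin precursor, higher (1.26). The signs of the enterocyte and Paneth medians turned under other settings, to 0.30 for enterocyte markers in a plain sum and to 0.03 for Paneth markers with clusters weighted equally. Markers of T and intraepithelial lymphocytes had a median of 1.60 over 6 members, and 3.92 with members at 0 in the young library set at their bound, but rested on very few cells: 0 young and 3 old cells held UMIs of at least 3 of these markers, and 564 of the 573 old UMIs of Gzma, a granule protease of killer lymphocytes, lay in 2 cells. Myeloid markers had a median of 1.06 over 6 members, with 0 young and 1 old cell holding at least 3. The lists for B and plasma cells, stromal and endothelial cells, and red blood cells had fewer than 3 members with 50 counts and gave no median. Leaving out cells with 3 immune markers changed none of the 24 named genes to under 2-fold.

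**Figure D3:**
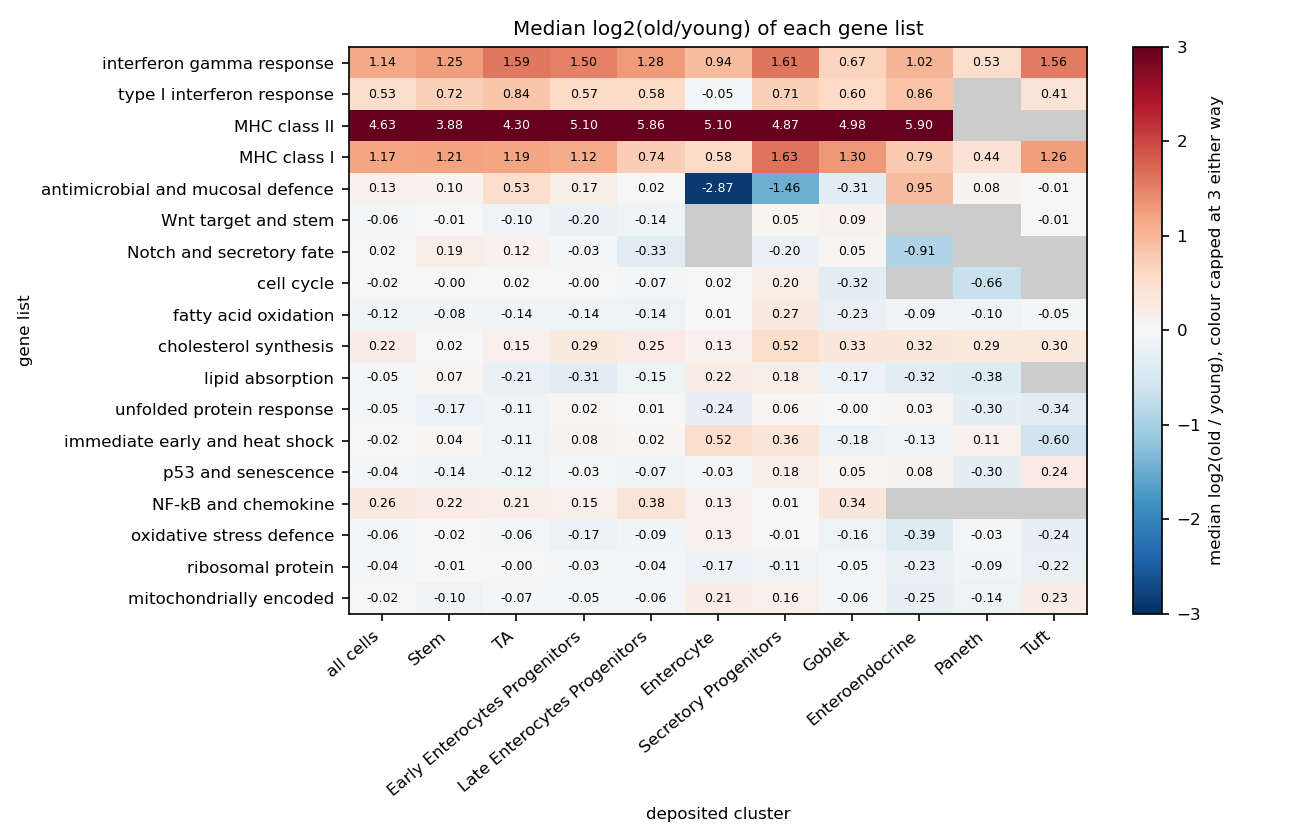
Median log2 ratio of old to young (colour and number) for the 18 gene lists (rows of the map) over all cells and in each deposited cluster (columns); grey marks fewer than 3 measured members, and colour is capped at 3 either way. MHC class II medians lie between 3.88 (Stem) and 5.90 (Enteroendocrine, where it was 4.63 without cells holding 3 immune markers) in the 8 clusters with a value, and interferon gamma medians between 0.53 (Paneth) and 1.61 (Secretory Progenitors).

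In the Stem cluster (1065 young and 559 old cells), class II genes were again much higher in the old library. H2-Aa was 87.2-fold higher in the old library (interval 68.9 to 112), at 5.75 and 501 CPM, with UMIs in 4.23% of young and 73.0% of old Stem cells. H2-Eb1 was 32.6-fold higher, H2-Ab1 21.7-fold, Cd74 17.6-fold, H2-Q7 18.7-fold and H2-DMb1 14.5-fold, and Iigp1 had 0 young and 65 old counts, at least 39.1-fold higher. In the other direction Zbtb16, a zinc finger transcription factor known to respond to glucocorticoids, had 138 young counts and 0 old counts, at least 25.5-fold lower, Sgk1 was 8.53-fold lower (interval 5.30 to 14.6) and Fkbp5 4.00-fold lower (interval 2.88 to 5.70). The MHC class II list had a median of 3.88 in Stem cells, MHC class I 1.21, the interferon gamma response 1.25 and Wnt target and stem -0.01.

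Wfdc10 was 10.6-fold lower in old Stem cells, Nrn1 5.63-fold and Cpm, a membrane carboxypeptidase, 5.75-fold lower. Tceal8 had 53 young and 0 old counts, at least 9.80-fold lower. Bex1, a small adaptor protein, had 74 counts against 1 (41.0-fold lower, interval 7.14 to 1643), and Amotl1, a junction protein, 49 against 1 (27.2-fold lower, interval 4.65 to 1095). The rule also took 4 hormone genes whose counts lay in single cells: 99.3% of the old counts of Sst, 95.7% of Gip and 100% of Iapp came from 1 old cell each, and 95.8% of the young counts of Gcg from 1 young cell.

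Class II UMIs were found in most old Stem cells, not in a few. With each cell thinned to 3600 UMIs and the counts of 6 class II genes added, the median was 18 UMIs in old and 0 in young Stem cells. Of the old Stem cells, 135 (24.2%, interval 20.7 to 27.9%) held 0 to 2 of these UMIs, 56 held 3 to 7 and 368 held 8 or more, whereas 957 of 1065 young Stem cells held 0 to 2. The summed CPM of the 8 measured class II genes was 301 in young and 4789 in old Stem cells, and it was higher in the old library in each of the 10 clusters, from 12.7-fold in Tuft upward. In Enteroendocrine it was 40.8-fold higher, but 19.4-fold once 2 old cells with at least 3 immune markers were left out, and 53.8% of old Enteroendocrine cells held 0 to 2 class II UMIs at 3600 UMIs. These ranges of UMIs are not cell types, and the number of cells near their bounds is the 56 given.

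**Figure D4:**
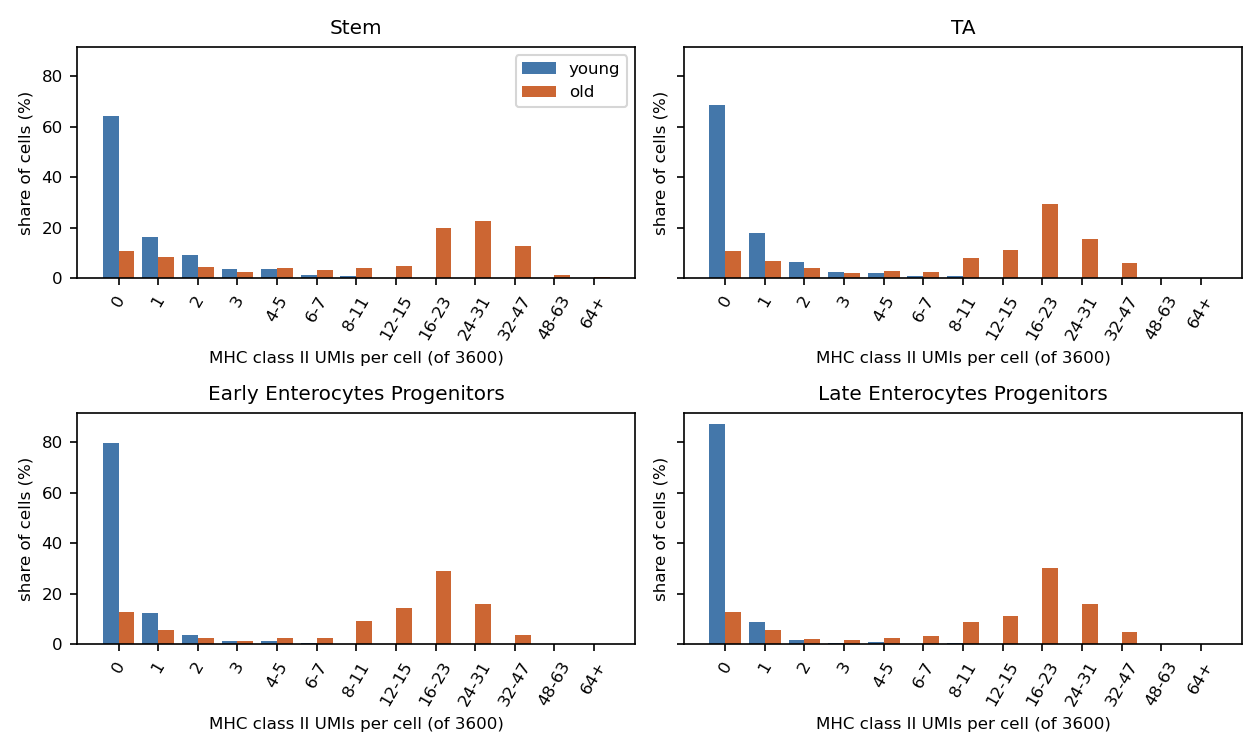
Share of cells in percent (y axis) by the number of UMIs of 6 MHC class II genes in a cell thinned to 3600 UMIs (x axis, bins that widen to the right) in 4 deposited clusters, young in blue and old in orange. Young cells gather at 0 to 2 UMIs, 89.9% of them in Stem, and old cells lie at 0 to 2 (24.2% in Stem) and at 8 or more (65.8% in Stem).

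In the other clusters with named genes, at least 1 class II gene or Cd74 was among them. H2-Aa was 85.2-fold higher in TA, the transit-amplifying cells (interval 69.7 to 105), 163-fold in Early Enterocytes Progenitors, 289-fold in Late Enterocytes Progenitors, 150-fold in Secretory Progenitors (interval 58.6 to 553) and 83.3-fold in Goblet (interval 32.3 to 307). In Enterocyte it had 2 young and 1272 old counts (397-fold higher, interval 109.6 to 3280) and in Enteroendocrine 0 and 170, at least 40.3-fold higher, with 58.2% of the old counts in 1 cell. H2-Eb1 was named in TA, Early Enterocytes Progenitors and Enterocyte, Cd74 in Early and Late Enterocytes Progenitors, Goblet and Paneth (33.6-fold higher), H2-Ab1 in TA, and H2-DMb1 in Enterocyte, Late Enterocytes Progenitors and Goblet.

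Of the genes lower in old cells, Nrn1 was 9.03-fold lower in TA and 24.9-fold lower in Early Enterocytes Progenitors (113 against 4 counts), and Zbtb16 had 71 young and 0 old counts in TA, at least 15.5-fold lower. Mt2, a metal-binding protein, was 6.19-fold lower in Early Enterocytes Progenitors, and in Late Enterocytes Progenitors Fkbp5 was 7.26-fold, Gm21814 7.08-fold and E230001N04Rik 12.3-fold lower; Fkbp5 was 5.72-fold lower in Secretory Progenitors. In Goblet cells Mptx1 was 13.6-fold lower (interval 10.5 to 17.8), from 305 to 22.4 CPM, Hmgcs2 4.97-fold and Mettl7b, a lipid droplet associated methyltransferase, 3.59-fold lower. In Paneth cells Reg3b was 4.81-fold lower, Agt, the angiotensin precursor, 5.96-fold, and Pdia2, a protein disulfide isomerase, had 51 counts against 1 (24.6-fold, interval 4.22 to 989). Ceacam10, a cell adhesion protein, was 9.76-fold higher and Zg16, a mucus lectin, 18.3-fold higher, with 45.2% of its old counts in 1 cell.

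The remaining genes taken in these clusters lay mostly in single cells. In Enterocyte, 96.2% of the young counts of Clps and of Gm14851 and 95.3% of Defa26 came from 1 cell. In Enteroendocrine, 100% of the old counts of Retnla and 99.03% of Apoe came from 1 cell, and Afp was 47.0-fold lower with young counts in 3 cells; Alb (13.5-fold) and Rnase1 (5.96-fold) were lower there too, on 48 and 55 young counts. In Secretory Progenitors, 100% of Gzma and 99.6% of Ccl5 came from 1 old cell, and for Gm14851 and Clps 1 cell held 58.9% and 52.8% of young and 76.0% and 80.9% of old counts. In Early Enterocytes Progenitors, 60.2% of the young Sst counts came from 1 cell. Gm29797 was lower in old TA cells (93 young counts in 15 cells and 3 old counts, 20.3-fold, interval 6.73 to 100.1).

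In the share of cells, the deposited Stem and TA clusters were smaller and the Goblet, Tuft and Enterocyte clusters larger in the old library. Stem cells made up 26.5% of young (interval 25.2 to 27.9%) and 15.1% of old cells (14.0 to 16.3%), a difference of -11.4 percentage points, and TA cells 24.4% and 16.8% (-7.60 points). Goblet cells, which secrete mucus, made up 3.81% (3.24 to 4.45%) and 7.34% (6.52 to 8.23%), Tuft cells, the chemosensory type, 0.722% and 1.57%, Enterocyte cells 2.91% and 5.91%, and Late Enterocytes Progenitors 11.2% and 14.6%. Early Enterocytes Progenitors (22.3% and 21.5%) and Paneth cells (1.92% and 1.38%) differed by -0.884 and -0.541 points, with intervals of the difference that included 0. Secretory Progenitors made up 4.91% and 13.7%, and 7.05% of old cells at or over the lowest young UMI total.

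These shares depended on how cells were assigned. In an own clustering of the counts, the difference was -2.06 points for Stem (interval -3.88 to -0.234), -1.09 for TA, with an interval (-2.81 to 0.644) that included 0, -7.53 for Early Enterocytes Progenitors and 1.49 for Enterocyte, and 5 of its 21 clusters were almost all from the old library, the largest with 548 old and 0 young cells drawn mainly from Stem. Of the 10 genes that led each deposited cluster, none differed 2-fold or more with age in TA, Goblet, Tuft, Enterocyte or Early Enterocytes Progenitors, 2 did in Stem (Hmgcs2 and Slc1a2), 1 each in Paneth and Late Enterocytes Progenitors, 4 in Secretory Progenitors and 5 in Enteroendocrine. For that reason the Enteroendocrine share (1.27% and 2.16%) is given with no direction. The name Early Enterocytes Progenitors is used as a label only: its 10 leading genes held 2 listed cycling markers and no listed enterocyte marker, while the enterocyte markers summed to 2865 CPM in it, 1329 CPM in TA and 6811 CPM in Late Enterocytes Progenitors. So is the name Secretory Progenitors: none of its 10 leading genes was a marker of a secretory type, 4 of them were lymphocyte markers with nearly all counts in single cells, its median total was 6036 UMIs in young and 4852 in old cells, and 54.8% of its old cells lay under the lowest young total.

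Counted without any cluster, markers of stem, goblet and tuft cells went the same way as the shares of those clusters, and genes of enterocytes differed among themselves. The share of cells with a UMI depends on the level per cell as well as on the number of cells. At a common composition Lgr5 was itself lower (log2 ratio -0.32), while Dclk1 stood at -0.05. At 3600 UMIs per cell, Lgr5 was seen in 6.33% of young and 3.73% of old cells (15.3% and 8.99% unthinned), against 0.445% and 0% (exact interval up to 0.680%) of Late Enterocytes Progenitors, which should lack it; their median totals were 13931 and 14255 UMIs. Over the plain sum of all cells, Lgr5 stood at 17.1 and 10.8 CPM. Muc2, the main mucin of goblet cells, was seen in 6.28% of young and 10.7% of old cells (10.8% and 16.5% unthinned), against 2.45% and 2.77% of Late Enterocytes Progenitors. Dclk1, a tuft cell kinase, was seen in 0.797% and 1.65% (1.07% and 2.13% unthinned), against 0.223% and 0.185% of Late Enterocytes Progenitors. Alpi, the alkaline phosphatase of enterocytes and a leading gene of Late Enterocytes Progenitors, was seen in 8.47% and 8.59% (18.3% and 16.1% unthinned), against 0.654% and 0.368% of Goblet cells, and stood at 37.6 and 36.3 CPM. Apoa1, which led the Enterocyte cluster, stood at 181 and 405 CPM in the plain sum, with UMIs in 24.7% and 24.6% of cells unthinned, Apoa4 at 50.1 and 51.2 CPM, and the enterocyte markers had a median log2 ratio of 0.30. Mki67 was seen in 33.6% and 31.9% (57.1% and 52.0% unthinned).

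**Figure D5:**
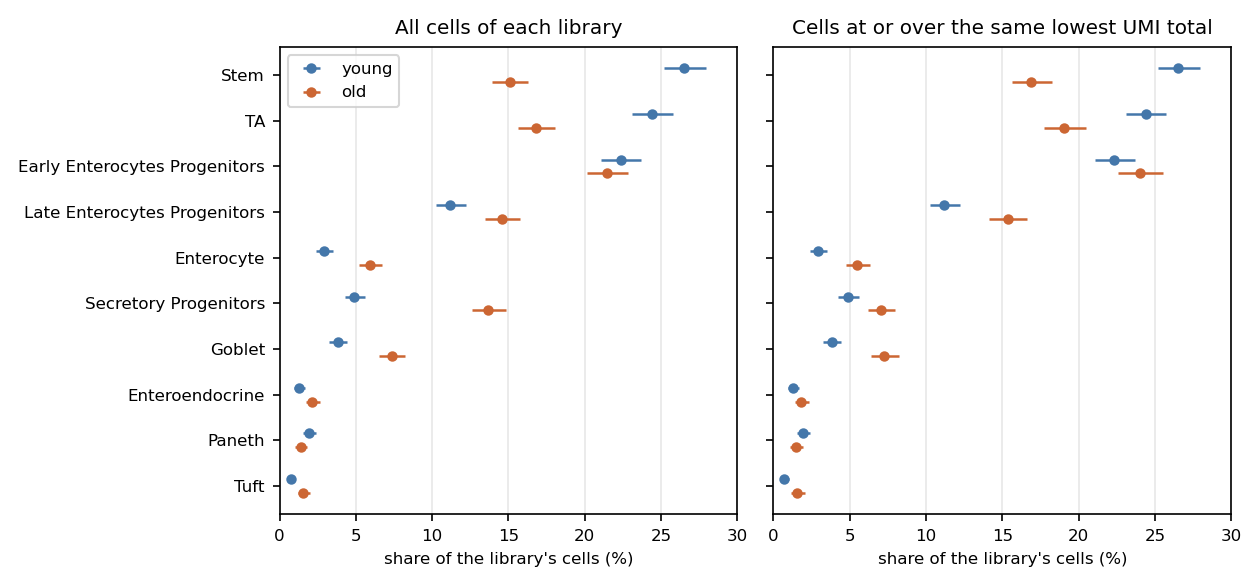
Share of each library's cells in percent (x axis) in the 10 deposited clusters (y axis), young in blue and old in orange, points with exact 95% intervals, for all cells (left) and for cells at or over 4997 UMIs (right). Stem stands at 26.5% and 15.1% on the left and at 26.5% and 16.9% on the right, and Secretory Progenitors at 4.91% and 13.7% on the left and at 4.91% and 7.05% on the right.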

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

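The tests on free RNA, on single antigen-presenting cells, on library preparation, on the UMI floor and on free gastric RNA were chosen after the results were seen, as were the values without the cell richest in Paneth markers; the tests on damaged cells, on gastric cells and on expression by crypt cells were written down before their values.

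Some defence genes went the opposite way in single clusters from their value over all cells, with counting intervals apart for the genes; none of these differences between clusters was tested. The antimicrobial and mucosal defence list had a median log2 ratio of 0.13 over all cells, against -2.87 in Enterocyte, -1.46 in Secretory Progenitors and -0.31 in Goblet. Reg3b stood at 1.48 over all cells, against -0.96 in Goblet (541 to 278 CPM) and -2.25 in Paneth (303 to 63.1 CPM), and Reg3g at 1.69 over all cells, against -0.98 in Paneth (887 to 451 CPM). In young Enterocyte cells, 90.6% of all Paneth marker UMIs lay in 1 cell, and without the richest cell of each age the Enterocyte median was -0.02 and that of Secretory Progenitors -0.78. For Reg3b, 1 young cell held 32.7% of the counts in Goblet and 22.7% in Paneth.

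The higher MHC class II genes in the old library were set against 3 technical explanations. Free RNA from other cells would load all clusters alike, but old TA cells held 70.8 class II UMIs per cell and old Tuft cells 4.79, a ratio of 14.8, which argues against it. A few antigen-presenting cells or doublets would leave most cells without these UMIs, but 75.8% of old Stem cells held at least 3 at the thinned depth, against 10.1% of young Stem cells, which argues against that too. A difference between the library preparations, or between the pools of mice for a reason other than age such as exposure to microbes, cannot be told apart from age, since there was 1 library per age. Age itself stays open and untested for the same reason.

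The higher share of Secretory Progenitors in the old library was set against 2 technical explanations. With a common UMI floor the share was 7.05% in old and 4.91% in young cells, a difference of 2.14 points with intervals apart, against 8.78 points over all cells. A common floor thus took away much of the difference between these 2 libraries but not the whole. The intervals cover counting error only, so with 1 library per age the rest cannot be told from spread between libraries. With cells over 10% mitochondrial UMIs left out as well it was 5.71% and 3.80%, a difference of 1.91 points with intervals apart, which argues against damaged cells as the whole cause. At a floor of 8000 UMIs the shares were 1.09% and 0.746% with intervals that overlap, so a shallower set of old cells over the common floor could still add to the difference. An effect of age on a secretory type stays open and untested, and the cluster's leading genes do not name such a type.

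The gastric transcripts of the old library (Gkn1, Gkn2 and Tff1, with 497 UMIs in old cells and 1 in young cells) were set against 3 explanations. Gastric cells among the sorted cells would concentrate them, but the 10 old cells with most held 7.44% of the UMIs, and Muc5ac, an abundant mucin of stomach surface cells, had 0 counts in both ages. Expression by crypt cells would scale with depth, but the deepest tertile of old cells held 0.607 times the UMIs per cell of the shallowest (interval 0.488 to 0.753), far under the ratio of their totals of 3.62. The outcome written down beforehand had asked for an interval that included 1, and the value lay under it. Depth also differed by cluster, with median totals of 4852 UMIs in old Secretory Progenitors and 16968 UMIs in old TA. They held 0.142 and 0.127 UMIs of these genes per cell. The tertiles were taken over all old cells, so the ratio does not exclude expression limited to shallow clusters. Free RNA from gastric tissue would load clusters alike. Among clusters of at least 200 old cells, the ratio of the highest to the lowest was 1.42 (0.157 and 0.111 UMIs per cell). That limit on size was set after the results were seen, and none was set for the class II genes. The smaller clusters lay further apart, from 0.0517 UMIs per cell in Tuft (3 UMIs) to 0.314 in Paneth (16 UMIs). Free RNA would also give a depth ratio of 1, and the interval excluded that, so it stays open. This condition on depth was added after the value was seen. An effect of age on these genes was not tested.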

How the results depend on the processing

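Alternatives with a common UMI floor, with immune or enteroendocrine marker cells left out, without Secretory Progenitors, with the highest Scrublet scores left out or without cells rich in Paneth markers were chosen after the data were seen. No paired analysis was possible because the labels share no replicate numbers between ages, no library could be left out with 1 per age, and leaving out immune or stromal clusters was not run because no deposited cluster was made up of such cells (Secretory Progenitors, with 4 lymphocyte markers from single cells among its leading genes, was left out as an added alternative). Of the alternative values, 46 shares kept within their interval and 14 moved, 678 list medians kept, 31 moved and 4 reversed, 4593 single genes kept and 712 moved, and 101 counts of named genes kept and 7 moved. The MHC class II median stayed between 4.05 and 4.69, MHC class I between 0.97 and 1.22, and 22 to 24 of the 24 genes named over all cells stayed at least 2-fold apart. Depth limits genes under a few CPM, since the pseudocount of 1 CPM pulls their ratios toward 0.

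With own clustering the differences in share were -2.06 points for Stem, -1.09 for TA (its interval included 0), -7.53 for Early Enterocytes Progenitors, 1.49 for Enterocyte and 1.61 for Secretory Progenitors. At the common UMI floor they were -9.62 for Stem, -5.33 for TA, 1.68 for Early Enterocytes Progenitors and 2.14 for Secretory Progenitors, and with cells over 10% mitochondrial UMIs also left out -9.52, -5.47, 1.81 and 1.91. Without the lowest and highest 10% of cells by UMIs the Paneth difference was 0.294 (interval -0.0376 to 0.662), but this left 9 young and 17 old Paneth cells, which are the deepest cells, so it says nothing of their share. The interferon gamma median was 0.90 with equal weights, 0.93 with no minimum count and 0.82 with a pseudocount of 5 CPM; it was 0.77 in Early Enterocytes Progenitors and 1.26 in TA with no minimum, and 0.63 in Enterocyte with thinned cells. The type I interferon median was 0.71 in a plain sum, 0.73 with a pseudocount of 0.1 CPM and 0.25 with 5 CPM. In a plain sum, which keeps the difference in composition, Wnt target and stem stood at -0.30 and cell cycle at -0.10 (-0.067 without the extreme cells by UMIs). The median reversed for enterocyte markers in a plain sum (0.30) and for Paneth markers with equal weights (0.0285), with Paneth and goblet genes out of the totals (0.12) and with thinned cells (0.0041). At a minimum of 200 counts, 13 named genes were still measured in Stem and 3 each in Enteroendocrine, Late Enterocytes Progenitors and Paneth. A higher minimum only removes genes and leaves the ratios of the rest unchanged. That all of them stayed at least 2-fold apart was therefore fixed in advance. With thinned cells, 3 of 3 named genes still measured in Late Enterocytes Progenitors and 1 of 1 in Paneth stayed at least 2-fold apart. With the highest Scrublet scores left out 3 of 4 did in Enterocyte; the other was Gm14851 (-0.21), whose young counts lay mainly in 1 cell. The causes of the other changes were not tested.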

Other observations

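The tests on mice, gut segments or crypt patches and on counts not thinned were chosen after the results were seen, and the tests on shallow cells, on glucocorticoid targets and on time of day were written down before their values. Some of the glucocorticoid targets were also in lists fixed earlier, as given below.

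Hormone genes of the Enteroendocrine cluster differed in mixture between the libraries. Ghrl, ghrelin, stood at 40518 CPM in 51 young and 13662 CPM in 80 old cells (log2 ratio -1.57), while Chga, a granule protein of endocrine cells, stood at 3178 and 7035 CPM (1.15), Tac1 at 2377 and 5435 CPM (1.19) and Sct, secretin, at 3035 and 8090 CPM (1.41). Single cells held 33.9% of the young counts of Ghrl and 80.9% of the young counts of Gcg, the glucagon precursor, which stood at 3648 and 8161 CPM.

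Old Stem cells low in class II UMIs differed from those high in them in other genes. Hmgcs2 stood at 250.5 CPM in the 135 cells with 0 to 2 class II UMIs, 40.7 CPM in the 368 cells with 8 or more and 279 CPM in young Stem cells, and Gkn3 at 351, 106 and 341 CPM. In the same order, Reg3g stood at 99.9, 735 and 96.4 CPM. Fabp1, an enterocyte marker, stood at 358, 54.0 and 110 CPM, so the low range did not match young cells in every gene. In Late Enterocytes Progenitors, Fabp1 stood at 3572, 743 and 2005 CPM and Reg3b at 138, 7268 and 1098 CPM. Psmb8 had a median of 0 thinned UMIs in the low range, 3 in the high range and 0 in young Stem cells. Fkbp5 was low in both ranges, at 4.94 and 6.97 CPM against 23.95 CPM in young Stem cells.

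One hypothesis is that the low and high ranges of old Stem cells come from shallow cells. The ranges were taken after every cell had been thinned to 3600 UMIs, so unequal depth did not set them. At that depth 24.2% of old Stem cells held 0 to 2 class II UMIs. Poisson counts around their mean of 17.4 UMIs would leave 4.6e-04% of cells there. The median total before thinning was 12829 UMIs in the low and 12147 UMIs in the high range, a ratio of 1.06. That ratio met the outcome written down beforehand as speaking against shallow cells. Ranges set at equal depth make a ratio near 1 likely in advance, so the ratio cannot decide. On counts not thinned, 9.14% of the deepest tertile of old Stem cells (interval 5.41 to 14.2%) and 20.9% of the shallowest (15.3 to 27.4%) held 0 to 2 class II UMIs. The low share was larger in the shallowest tertile, with intervals apart, but cells of the deepest tertile held it too. The counts not thinned decide neither way. The share at equal depth, set beside the Poisson share, argues only against unequal drawing of UMIs as the cause of the low range in Stem. Another is that mice, gut segments or crypt patches within the old pool differed, so that whole crypts may be low or high. The share of old cells in the low range was then expected to be alike in clusters that come from every crypt; it lay between 20.7% and 24.2% in the Stem, TA and both enterocyte progenitor clusters, a ratio of 1.17, and at 17.2% in Secretory Progenitors. It was 36.8% in Goblet, 37.9% in Enterocyte, 53.8% in Enteroendocrine, 82.8% in Tuft and 90.2% in Paneth. A lower level of these genes in such cells would raise that share as well, and cells carry no mouse label, so differing mice or patches stay open, as does a switch inherited within cell lineages.

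Fkbp5, Sgk1, Zbtb16 and Mt2, which glucocorticoids are known to induce, and Hmgcs2 were all lower in the old library. A lower glucocorticoid response was taken from this as a hypothesis. Hmgcs2 did not follow Fkbp5 within old Stem cells. With 0 to 2 class II UMIs, Hmgcs2 stood at 250 CPM and Fkbp5 at 4.94 CPM, against 279 and 23.95 CPM in young Stem cells. With 8 or more, they stood at 40.7 and 6.97 CPM. In TA, Hmgcs2 stood at 156 CPM in the low range, 13.2 CPM in the high range and 162 CPM in young cells. Among 17 other measured targets, the median log2 ratio was -0.0866 (percentile 3.74), with 1 at least 1.5-fold higher (Cebpd, 0.85) and 1 at least 1.5-fold lower (Mt1, -0.68). Of the 17, 10 lay below 0 and 7 above. After Mt1, the lowest were Per1 (-0.54), Sult1a1 (-0.51), Klf9 (-0.46), Tiparp (-0.35) and Tsc22d3 (-0.30). After Cebpd, the highest was Lpin1 (0.34). Pdk4 (0.33), Nfkbia (0.26) and Dusp1 (-0.02) among the 17 targets were also in lists fixed earlier, so their values were not new. A median without them was not taken, and this result decides neither way. A different time of day at collection was tested on Dbp, Nr1d1, Nr1d2, Per2 and Per3, whose median was -0.16 (interval -0.41 to 0.33) beside 0.11 for Arntl, which met the outcome written down beforehand as speaking against it; the interval was asked for only after the values were seen, and it was too wide to decide. Over the other listed clock genes the median was -0.02 (8 measured), and over the gastric list 1.27 (6 measured). The gastric list was written after the first look at the values and holds Gkn1 (1.78), Gkn2 (2.65) and Tff1 (2.02). Its median therefore adds no support to them. The remaining measured members were Tff2 (0.76), Atp4a (0.41) and Pgc (-0.32). Stress at collection, time of day and age stay open.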
